A study of Homo sapiens with 32 samples.

How the data were processed

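The data are gene counts of 32 RNA-seq libraries from HEK293 cells incubated with 4-thiouracil for 0, 5, 15 or 30 min. Per the labels, each time has 2 biological replicates (called cultures here), each with 2 cDNA preparations of 2 libraries, and each library has a tagmentation number. At 0 min the libraries of a cDNA share that number in the labels and in the file headers. The growth protocol refers to a published transient transcriptome sequencing method and the extraction protocol to a published single-cell tagged reverse transcription method. Neither label says whether tagged RNA was purified, whether molecular identifiers were counted, or what the 0 min cells received.

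The authors deposited 1 table of whole-number counts for 32738 gene entries, of which 18789 had a count in any library and 91 symbols stood on more than 1 entry. Whether a count is a read or a molecule is not given in the sources used here, nor is the strand used in counting. Reads were aligned to hg19 with STAR, per the submitters' processing notes, and the version is not given in the sources used here. Columns were matched to samples by the barcode in the label and the header. The header and the labels give different tagmentation numbers for 4 libraries of culture 2 at 0 min, which changes no sum. The table used holds no spike-in, repeat, or separate spliced and unspliced entries, so comparisons of these were not analysed here. No coordinates are given, because the annotation used here is of another build.

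Counts were summed over the 4 libraries of each culture, giving 8 samples of 776871 to 1396056 counts. All 16 pairs of libraries made from 1 cDNA differed by less than sampling noise by a chi-square test on genes with at least 10 counts in the pair, and were not used as separate samples. On simulated libraries the same measure gave 0.986 per degree of freedom with counting error alone, 3.49 with a coefficient of variation of 20% added, and 0.0529 when the same molecules were counted again. Counting intervals treat each count as independent and are therefore narrower than they should be.

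Differences between times were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling, genes kept by filterByExpr (10439), 1 fit over all 8 cultures with 4 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0235, a biological coefficient of variation of 15.3%. Tests are two-sided, except the chi-square tests of library pairs, which are one-sided in each direction. With 2 cultures against 2 an exact permutation test of a single gene cannot go below p = 0.333, so none was used. Contrasts were 5, 15 and 30 min against 0 min, 30 against 5 min, and the steps from 5 to 15 and 15 to 30 min. Expression levels are TMM-scaled CPM, given as mean and SD of 2 cultures; summed list levels are CPM of the total. Genes at 0 in both cultures of a time are given as at least so many fold against a floor of 3 counts over both cultures, and genes with 1 to 3 counts as a ratio with an exact 95% counting interval.

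Gene lists (20) and the naming rule were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, 80 tests over the 4 main contrasts adjusted together and 40 over the 2 steps, and again with a correlation estimated per list. That estimate rests on 4 residual degrees of freedom and is imprecise. A call lost with it therefore cannot be put down to correlation between genes alone. The rule names, for each main contrast, the 6 largest increases and 6 largest decreases with adjusted p under 0.05, mean CPM of at least 10 and no overlap between cultures, plus the 2 most abundant tested members of each list. Other genes named in the text are said to be chosen after their values were seen. ATF3 and PPP1R15A are on both the immediate-early and stress response lists, BTG2 on the immediate-early and p53 lists, and SESN2 on the stress response and p53 lists. TFRC is expressed by dividing cells of many types although it stands on the erythroid list.

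The pipeline was tested on simulated counts for the 0 to 5 min comparison with 10439 genes, of which 200 were changed. It recovered 2.99% of genes changed by 1.5-fold, 34.3% of those changed by 2-fold and 69.7% of those changed by 4-fold, with 2 false calls among 73. A simulated list raised by 0.5 was called at adjusted p = 2.82e-15 by camera, and 0 of 80 random lists were. The simulated genes were drawn independently of each other. The random lists therefore do not test for false calls that come from correlation between genes. With 200 genes changed, most changes of 2-fold or less were thus missed. A gene that did not pass a test may have changed. Where many more genes change, as in the comparisons with 0 min, the adjustment is less strict and these percentages do not apply. Changes under 2-fold were called in the data: from 5 to 30 min 614 genes were higher and 681 lower, of which 509 and 102 by over 2-fold.

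Alternatives set before the data were examined were DESeq2 1.42.0 on the same sums, RLE size factors, total counts only, no low-count filter, a minimum mean CPM of 10, the culture number as a replicate block, all 32 libraries as samples in edgeR or in limma-voom with duplicateCorrelation, only the 2 times compared, each culture left out in turn, an estimated correlation for lists, and pseudocounts of 0.1 and 10 or a minimum of 100 CPM for the spread. Added after seeing the data were 1 library per cDNA and counts thinned to the shallowest culture. Gene span and exonic length came from GENCODE annotation of another build, joined by symbol (9527 of 10439 genes, 91.3%), and were used as lengths only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.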

Results

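RNA of HEK293 cells, an established human line of embryonic kidney origin, was counted after incubation with 4-thiouracil for 0, 5, 15 or 30 min. 4-Thiouracil is a sulphur-bearing form of uracil that is used to tag RNA made during an incubation. The labels name polyadenylated RNA, but do not say whether tagged RNA was separated from the rest or what the 0 min cells received. The values are therefore shares of the counted RNA, and which pool of RNA was counted at each time is left open. Each of the 4 times had 2 cultures, called biological replicates in the labels, and each culture had 2 cDNA preparations with 2 libraries each, giving 32 libraries in all. The libraries were made by tagmentation (fragmenting and tagging by a transposase), and at 0 min the libraries of a cDNA carry the same tagmentation number in the labels.

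Total counts per library ranged from 188686 to 381471. Summed over the 4 libraries of a culture they ranged from 776871 in culture 1 at 5 min to 1396056 in culture 1 at 30 min. The 0 min cultures held 1217384 and 1022116 counts, the other 5 min culture 1298475, the 15 min cultures 1339808 and 1347710, and culture 2 at 30 min 1343632. In all 16 pairs of libraries made from the same cDNA the counts differed by less than the sampling noise (chi-square per degree of freedom 0.327 to 0.594). In all 32 pairs of libraries from different cDNA of 1 culture they differed by more than it (1.14 to 2.29). The libraries of 1 cDNA were thus not separate samples, and all libraries of a culture were summed and counted as 1 sample, so that n = 2 cultures per time throughout.

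The make-up of the counted RNA differed most between 0 min and the later times. Cytosolic ribosomal protein mRNAs, which encode the proteins of the ribosome, took 19.3% ± 1.53 (SD, n = 2) of the counts at 0 min, 10.7% ± 1.05 at 5 min, 10.7% ± 1.33 at 15 min and 7.66% ± 0.408 at 30 min. The 50 most abundant genes took 22.8% ± 1.39 at 0 min and 11.8% ± 0.987, 12.5% ± 1.31 and 11.2% ± 0.408 at the later times. Immediate-early mRNAs, the transcripts that growth factors and stress induce within minutes, summed to 1044 ± 54.2 CPM (counts scaled to a common library size) of the total at 0 min, 1571 ± 49.5 at 5 min, 4580 ± 494 at 15 min and 9892 ± 921 at 30 min. Across genes, log2 CPM correlated at r = 0.922 to 0.959 between the cultures of 1 time (4 pairs), at 0.887 to 0.949 between 2 later times (12 pairs) and at 0.720 to 0.792 between 0 min and a later time (12 pairs), where genes are not independent replicates.

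**Figure D1:**
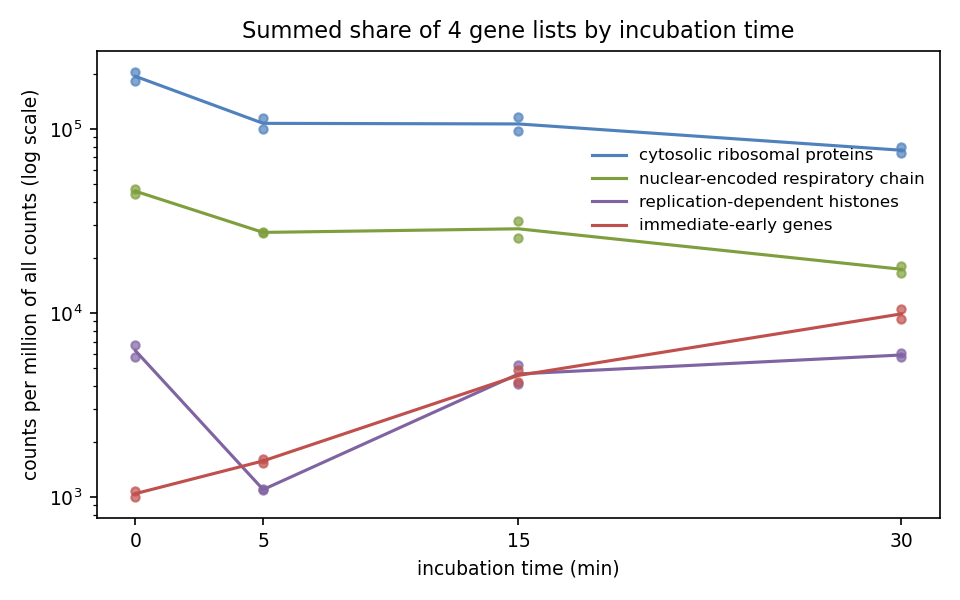
Summed CPM of the total (vertical log axis) against incubation time in min for 4 gene lists fixed before the data were examined. Dots are the 2 cultures of each time and the line joins their means: immediate-early genes went from 1044 to 9892, while the ribosomal proteins went from 193227 to 76648.

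Because the shares moved this far, the scaling between cultures mattered for every comparison with 0 min. With TMM scaling, which sets the bulk of genes level, the median log2 fold change over all 10439 genes tested was 0.10 from 0 to 5 min, 0.19 from 0 to 15 min and 0.35 from 0 to 30 min. With total counts as the only scaling it was 0.83, 0.96 and 1.22, and with RLE size factors 0.04, 0.09 and 0.18. All fold changes are log2 values with TMM scaling unless stated otherwise, and say how a gene moved relative to the bulk of genes, not how many molecules a cell held. The p-values rest on 2 cultures per time, and counting intervals and floors cover counting error only. Each SE is the size of the log2 fold change divided by the square root of the test's F value. For genes with few counts it can lie below counting error. List members named beyond the 2 most abundant of each list, such as EIF4B, HK2, MT-CO1 and PFKM, were chosen after their values were seen.

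The comparison of 5 min with 0 min asked how the counted RNA differed after the shortest incubation. Most cytosolic ribosomal protein, respiratory chain and heat shock genes fell. Of 79 cytosolic ribosomal protein genes, 76 fell, 0 rose and 3 did not pass the test (76 fell and 1 rose adjusted over the list alone), with a median of -1.47. RPL8, of the large ribosomal subunit, fell by 1.95 (SE 0.22, adjusted p = 2.26e-09) from 19318 ± 2763 to 5014 ± 201 TMM-scaled CPM (SD, n = 2). Of 47 nuclear genes of the respiratory chain, which makes most cellular ATP, 44 fell and 0 rose (45 fell and 1 rose adjusted over the list alone), with a median of -1.45, among them the ATP synthase subunit ATP5E at -1.53 and the cytochrome c oxidase subunit COX7A2 at -1.25. HSPA8, a constitutive Hsp70 chaperone, fell by 2.97 (SE 0.21, adjusted p = 2.05e-13), as 13 of 16 heat shock genes did with 0 risen (13 fell adjusted over the list alone, median -1.42).

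Of 17 translation factors whose mRNAs begin with a pyrimidine tract, 14 fell and EIF4B rose by 1.46 (14 and 1 adjusted over the list alone, median -1.67), with the ribosome-associated GNB2L1 at -2.16 and TPT1 at -2.61. Of 16 glycolysis enzymes, 10 fell and HK2, which phosphorylates glucose, rose by 1.63 (10 and 1 adjusted over the list alone, median -1.36), with GAPDH at -1.81 and LDHB at -1.74. Of 39 ribosome biogenesis genes, 24 fell and 4 rose (25 and 4 adjusted over the list alone, median -1.14), with the nucleolar protein NPM1 at -2.33. Of 32 genes of the G2 and M phases of the cell cycle, 17 fell and 3 rose (18 and 3 adjusted over the list alone, median -0.86), with CKS2 at -1.61. Of 11 mitochondrially encoded transcripts, 6 fell and 0 rose (6 adjusted over the list alone, median -0.88), with MT-ND1 at -1.41 and MT-ND3 at -1.36, though this list was no longer past its test with total counts (median -0.14). Of 29 genes of the unfolded protein and integrated stress responses, 11 fell and 4 rose (11 and 4 adjusted over the list alone), with the chaperone HSPA5 at -2.13 and the transcription factor ATF4 at -2.28; the list's median of -0.72 turned to 0.01 with total counts.

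The histone list had the lowest median of all lists. Of 23 replication-dependent histone genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -2.24. HIST1H4C, an H4 gene, fell from 7784 ± 1211 to 537 ± 26.8 TMM-scaled CPM (-3.86, SE 0.22, adjusted p = 4.8e-15) and HIST1H2BK fell by 2.36, while HIST1H2BJ rose by 2.18 and HIST1H3D by 0.97. HIST1H2BJ and HIST1H3D were named after their values were seen. Histone genes have near-identical copies, so the counts of single members are uncertain. The labels name polyadenylated RNA, so how far these counts stand for all histone transcripts is left open at every time.

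Among the 6 largest decreases past the test with no overlap between the cultures, which 1 in 3 genes would meet by chance, were RMRP and EIF3I. RMRP, the RNA component of a ribonuclease that processes ribosomal and mitochondrial RNA, went from 211 ± 16.3 to 4.72 ± 6.68 TMM-scaled CPM (-5.81, SE 0.55, adjusted p = 7.4e-11). At 5 min RMRP stood at 9.44 in culture 1 and 0 in culture 2, so the size of its fall is uncertain. EIF3I, a subunit of a translation initiation factor, fell from 1584 ± 75.7 to 93.8 ± 4.19 (-4.07, SE 0.23, adjusted p = 2.94e-15). The others were APOBEC3C at -4.16, SLC50A1, a sugar transporter, at -3.78, NABP2 at -3.73 and HIST1H4C. The 6 largest increases were in genes with 0 or 1 count at 0 min. FAM160A1 was at least 26.7-fold higher than the floor of 3 counts over both 0 min cultures, with 52.0 ± 13.4 TMM-scaled CPM at 5 min, CA5B, a mitochondrial carbonic anhydrase, at least 17.2-fold and TMTC1 at least 11.5-fold. PSMD6-AS2 was at least 18.9-fold higher, but it is antisense to another gene and the strand used in counting is not given in the sources used here. The RNA-binding protein gene ELAVL2 was 71.7 times as high (95% counting interval 12.6 to 2857) and the noncoding RP4-714D9.2 48.2 times (8.39 to 1930).

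The remaining lists were not called from 0 to 5 min, although some of their members changed. Of 31 immediate-early genes, DUSP1 and KLF6 rose, by 1.44 and 1.23, while 6 fell (4 adjusted over the list alone), among them the AP-1 subunit FOS at -2.72, with 5 counts left at 5 min, GADD45B at -1.72 and CYR61 at -1.40; these members were named after their values were seen. The list's median of -0.39 turned to 0.32 with total counts, and ID2 and HES1 did not pass the test. Of 51 zinc finger transcription factors, 17 rose and 6 fell (15 and 6 adjusted over the list alone), with ZNF644 at 1.82. Of 7 nuclear noncoding RNAs, 4 rose and 1 fell (4 and 1 adjusted over the list alone). NEAT1, which builds nuclear paraspeckles, rose by 1.08, as did KCNQ1OT1, FTX and TUG1, and MALAT1 fell by 1.22. SR splicing factors and CLK kinases (5 rose, 4 fell of 15, among them SRSF3 at -2.01), snoRNA host genes (2 rose, 4 fell of 10), p53 targets (3 rose, 4 fell of 20, with PMAIP1 at -1.82), cholesterol biosynthesis genes (4 rose, 10 fell of 21, with IDI1 at -1.71 and SQLE at 0.72) and interferon-stimulated genes (2 rose, 3 fell of 8) were not called as lists. For the interferon list the median of 0.41 and the test's downward direction differed in sign. Adjusted over the list alone these counts were 5 and 4, 2 and 4, 3 and 2, 4 and 10, and 2 and 3.

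In total 5710 of 10439 genes differed between 0 and 5 min (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), 2998 higher and 2712 lower, of which 2672 and 2258 by over 2-fold. By the camera test with its preset correlation of 0.01 the called lists had adjusted p = 7.61e-27 (ribosomal proteins), 4.44e-18 (respiratory chain), 1.93e-07 (translation factors), 5.62e-07 (heat shock), 2.99e-05 (glycolysis and ribosome biogenesis), 0.000546 (G2 and M phases), 0.00059 (histones), 0.00385 (stress responses) and 0.012 (mitochondrial transcripts). None held with an estimated correlation, where adjusted p = 0.257, 0.238, 0.203, 0.217, 0.182, 0.204, 0.143, 0.218, 0.238 and 0.405 in that order. The correlation was estimated from 4 residual degrees of freedom, so why the calls were lost is left open here and in the later comparisons. Across 9330 protein-coding genes the change from 0 to 5 min rose with the annotated span of the gene (Spearman rho 0.558 across genes, which are not independent replicates). With total counts as the only scaling 4461 genes were higher and 1448 lower. With a replicate block 2928 were higher and 2664 lower. With RLE the balance was near level (2855 higher, 2828 lower), and in DESeq2 it turned (2567 and 2596).

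**Figure D2:**
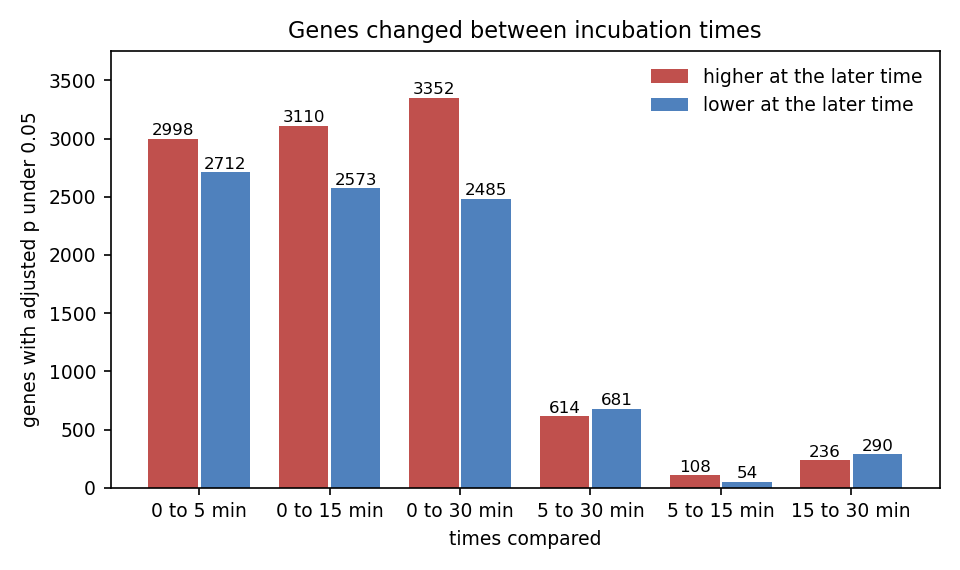
Number of genes higher and lower (bars from 0, of 10439 tested, adjusted p under 0.05) in each comparison of incubation times. The comparisons with 0 min called 5683 to 5837 genes, and 5 to 15 min called 162.

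At 15 min, compared with 0 min to ask how far the picture had moved after the middle incubation, most ribosomal protein, respiratory chain and heat shock genes stood lower and 15 of 31 immediate-early genes stood higher. Of the 79 ribosomal protein genes, 78 fell and RPL7 rose by 0.93 (78 and 1 adjusted over the list alone, median -1.49), with RPL8 at -1.87 (SE 0.22, adjusted p = 6.26e-09). RPL7 was named after its value was seen, and ribosomal protein genes have many processed pseudogenes that could share reads with them. Of the 47 respiratory chain genes, 46 fell and 0 rose (46 adjusted over the list alone, median -1.40). Of 31 immediate-early genes, 15 rose and 0 fell (15 adjusted over the list alone, median 1.29, or 1.21 with genes at 0 counts placed at their bound; adjusted p = 0.377 with an estimated correlation). ID2, an inhibitor of helix-loop-helix transcription factors, rose by 1.18 to 1322 ± 98.8 TMM-scaled CPM (SE 0.19, adjusted p = 1.8e-06), and HES1, a repressor in Notch signalling, rose by 1.29 to 735 ± 2.40 (SE 0.20, adjusted p = 1.27e-06).

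Of 51 zinc finger transcription factors, 20 rose, 3 fell and 28 did not pass the test (20 and 2 adjusted over the list alone, median 0.83), with ZNF644 at 1.58. This list's call was lost with an estimated correlation (adjusted p = 0.377). Translation factors (14 fell, EIF4B rose, of 17), heat shock genes (13 fell, 0 rose, of 16), glycolysis enzymes (10 fell, HK2 rose, of 16), ribosome biogenesis genes (25 fell, 3 rose, of 39), G2 and M phase genes (22 fell, 2 rose, of 32), cholesterol biosynthesis genes (11 fell, 3 rose, of 21) and mitochondrial transcripts (7 fell, 0 rose, of 11) were lower. Adjusted over the list alone the counts that fell and rose were 14 and 1, 13 and 0, 10 and 1, 25 and 3, 22 and 3, 11 and 3, and 8 and 0. The mitochondrial median of -0.54 turned to 0.24 with total counts, and the list's call was lost there, with 1 library per cDNA and without culture 2 at 0 min. Of 23 histone genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone), with HIST1H4C at -1.64 and HIST1H2BK at -1.39. Of the stress response genes, 7 rose and 10 fell (8 and 10 adjusted over the list alone), and PMAIP1, a p53 target that promotes apoptosis, was at 0.41 (SE 0.18, adjusted p = 0.0546), and past the test without culture 2 at 0, 5 or 15 min (0.63, 0.44 and 0.51). Without culture 1 at 0 min the stress response list was called, with a median of -0.51. Also not called were SR factors and CLK kinases (5 rose, 3 fell), snoRNA hosts (2 and 3), nuclear noncoding RNAs (4 and 1), p53 targets (5 and 2) and interferon genes (2 and 3), with the same counts adjusted over the list alone.

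Of the 6 largest increases from 0 to 15 min, each from 0 counts at 0 min, ZBTB17, a partner of MYC, was at least 12.7-fold higher and HEXIM2, an inhibitor of the elongation factor P-TEFb, at least 11.3-fold. FAM160A1, CA5B, PSMD6-AS2 and RP11-287D1.3 were at least 13.1-fold, 11.4-fold, 16.3-fold and 11.8-fold higher, where PSMD6-AS2 is antisense and the strand is not known. The largest decreases were RMRP at -6.09, ZNF358 at -3.95, RP11-139H15.1 at -3.85, SLC50A1 at -3.70, CRYL1 at -3.60 and APOBEC3C at -3.57. RP11-139H15.1 did not pass the test without culture 1 at 0 min, where its change was -3.10. In all 5683 genes differed, 3110 higher and 2573 lower, of which 2734 and 2075 by over 2-fold. With total counts 4901 were higher and 1307 lower, with RLE 2874 and 2758, and in DESeq2 2536 and 2499.

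The called lists from 0 to 15 min had camera adjusted p = 2.8e-32 (ribosomal proteins), 2.85e-20 (respiratory chain), 1.59e-08 (translation factors), 3.24e-07 (heat shock), 2.56e-06 (glycolysis), 3.73e-06 (ribosome biogenesis), 3.76e-05 (G2 and M phases), 0.000169 (immediate-early), 0.00742 (cholesterol), 0.012 (zinc fingers) and 0.0269 (mitochondrial transcripts). With an estimated correlation none held, at adjusted p = 0.218, 0.218, 0.188, 0.203, 0.143, 0.188, 0.143, 0.377, 0.182, 0.377 and 0.467 in that order.

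At 30 min, compared with 0 min to ask what the longest incubation had changed, every one of the 31 immediate-early genes tested had risen (31 adjusted over the list alone), with a median of 2.81, or 2.75 with genes at 0 counts placed at their bound. ID2 rose by 1.54 to 1698 ± 259 TMM-scaled CPM and HES1 by 1.71 to 983 ± 211 (SD, n = 2). NR4A3, a nuclear receptor of the immediate-early kind that was not on the list, had 58.6 ± 6.34 and was at least 28.8-fold higher than the floor of 3 counts over both 0 min cultures. Of 79 ribosomal protein genes, 77 fell and RPL7 rose by 0.77 (77 and 1 adjusted over the list alone, median -2.03), and RPL8 and RPL35 stood at -2.60 and -2.56 (SE 0.22 each). Of 47 respiratory chain genes, 46 fell and 0 rose (46 adjusted over the list alone, median -2.24), with ATP5E at -2.33 (SE 0.21, adjusted p = 1.39e-11) and COX7A2 at -2.23.

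Translation factors (14 of 17 fell, EIF4B rose, median -1.73), glycolysis enzymes (10 of 16 fell, HK2 rose, median -1.89), heat shock genes (10 of 16 fell, 1 rose, median -1.35), G2 and M phase genes (18 of 32 fell, 3 rose) and ribosome biogenesis genes (23 of 39 fell, 5 rose) were lower, with GNB2L1 at -2.74, GAPDH at -2.20, LDHB at -2.29, HSPA8 at -1.48 and NPM1 at -2.66. Adjusted over the list alone the counts that fell and rose were 14 and 1, 11 and 1, 11 and 1, 19 and 3, and 23 and 6. The median of the G2 and M phase list was -0.75 with TMM and 0.13 with total counts, and that of ribosome biogenesis -0.73 and 0.14. Of 51 zinc finger genes, 19 rose, 2 fell and 30 did not pass the test (19 and 1 adjusted over the list alone, median 1.01). This list's call was lost with an estimated correlation (adjusted p = 0.388). PMAIP1 rose by 1.55 (SE 0.18, adjusted p = 5.08e-09) and NEAT1 by 1.58, and MALAT1 fell by 1.40. The snoRNA hosts SNHG15 and TAF1D rose by 1.23 and 1.00, among 7 risen and 2 fallen of 10. Histones (4 rose, 6 fell), stress response genes (9 and 9), p53 targets (7 and 3), SR factors and CLK kinases (8 and 2), nuclear noncoding RNAs (5 and 1), mitochondrial transcripts (2 and 4), cholesterol genes (5 and 9) and interferon genes (1 and 1) were, like the snoRNA hosts, not called as lists. Adjusted over the list alone these were 3 and 6, 9 and 9, 7 and 3, 8 and 3, 5 and 2, 2 and 4, 5 and 10, and 1 and 1, and 7 and 2 for the hosts.

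Of the other large increases from 0 to 30 min, RPS10-NUDT3, a read-through transcript that shares exons with RPS10 and NUDT3, was at least 17.9-fold higher, the microRNA host MIR22HG at least 11.6-fold, HEXIM2 at least 11.2-fold, FAM160A1 at least 12.4-fold and the antisense PSMD6-AS2 at least 14.2-fold. The largest decreases were RMRP at -6.07, EIF3I at -4.35 (SE 0.22, adjusted p = 3.15e-16), RFESD at -4.25 and NABP2 at -4.04. C10orf32 was 30.5 times as high at 0 min (95% counting interval 9.73 to 154) and MFAP2 20.8 times (6.43 to 107). In all 5837 genes differed, 3352 higher and 2485 lower, of which 2955 and 2038 by over 2-fold. With total counts 5622 were higher and 1331 lower, and with a replicate block 3287 and 2455. With RLE the balance was closer (2909 higher, 2761 lower), and in DESeq2 it turned (2489 and 2532).

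The called lists from 0 to 30 min had camera adjusted p = 8.07e-42 (ribosomal proteins), 9.44e-37 (respiratory chain), 1.8e-13 (immediate-early), 3.04e-09 (translation factors), 3.24e-07 (glycolysis), 9e-06 (heat shock), 0.000194 (ribosome biogenesis), 0.000206 (G2 and M phases) and 0.0153 (zinc fingers). With an estimated correlation none held, at adjusted p = 0.206, 0.182, 0.203, 0.182, 0.143, 0.218, 0.218, 0.143 and 0.388 in that order.

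The comparison of 30 min with 5 min used no 0 min culture in its contrast and asked what changed as the incubation lengthened. Immediate-early mRNAs rose strongly, 29 of 31, with a median of 3.07, or 3.00 with genes at 0 counts placed at their bound (30 adjusted over the list alone). FOS went from 1.77 ± 2.50 to 605 ± 84.5 TMM-scaled CPM (SD, n = 2), a change of 8.04 (adjusted p = 2.57e-17). Its few counts at 5 min leave the size of this change uncertain. EGR1, a zinc finger transcription factor of the same kind, went from 1.30 ± 0.165 to 295 ± 90.9 and was 223 times as high (95% counting interval 76.2 to 1085). The orphan nuclear receptors NR4A1 and NR4A3 were 67.7 (18.5 to 563) and 66.3 (18.1 to 552) times as high, the kinase PIM1 85.9 times (15.1 to 3421), and FOSB, at 35.1 ± 22.6, was at least 26.6-fold higher than the floor of 3 counts over both 5 min cultures.

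Of the most abundant members of the list, ID2 rose by 1.62 (SE 0.18, adjusted p = 6.94e-08) from 551 ± 38.1 to 1698 ± 259 TMM-scaled CPM, and HES1 by 1.87 from 270 ± 51.6 to 983 ± 211. Further members, named after their values were seen, were CYR61 at 5.39, CTGF at 4.60, IER2 at 4.10, the phosphatase DUSP1 at 4.07, JUN at 3.27 and MYC at 3.07. Only KLF4 (2.13, adjusted p = 0.156) and PPP1R15A (1.57, adjusted p = 0.208) of the list did not pass the test. Of the rule's 6 largest increases, FOSB had no adjusted p in DESeq2, which set it aside.

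**Figure D3:**
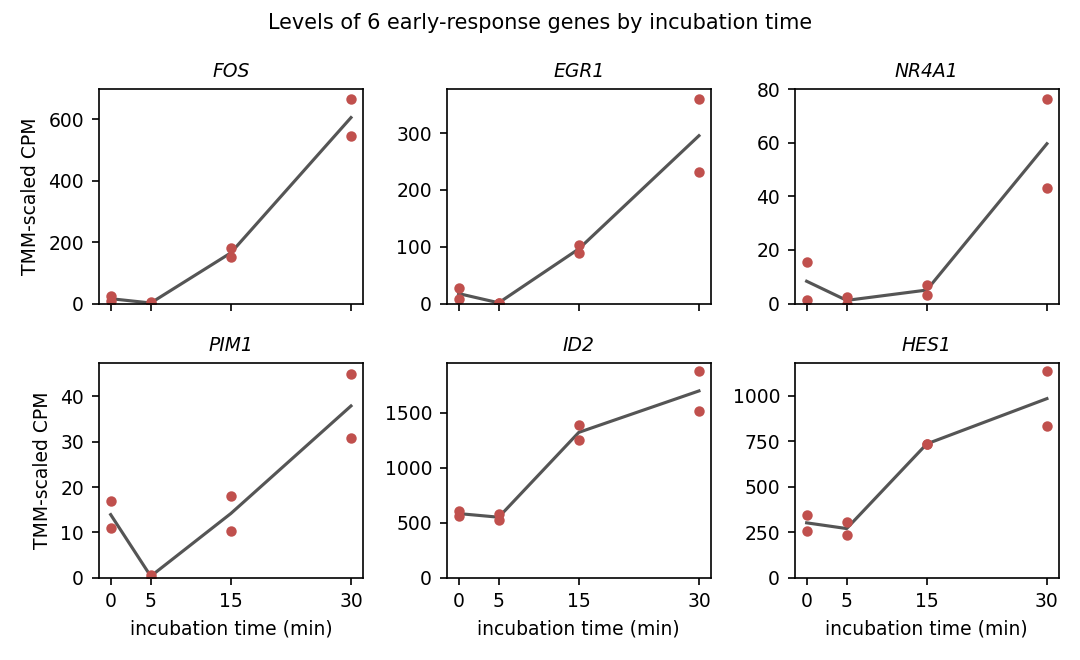
TMM-scaled CPM (vertical axis) of FOS, EGR1, NR4A1, PIM1, ID2 and HES1 in each culture (dots) against incubation time in min, with a line through the mean of the 2 cultures of each time. FOS stood at 1.77 at 5 min and 605 at 30 min, and ID2 at 551 and 1698.

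Some members of other lists rose with them, although most stress response, p53 and SR factor genes did not pass the test. Of 29 unfolded protein and integrated stress response genes, 8 rose and 0 fell (10 adjusted over the list alone, median 0.51), with ATF4, the factor that integrated stress signalling translates, at 2.12 (SE 0.19, adjusted p = 1.93e-10) and HSPA5 at 1.65. ATF3 at 4.04, which is also on the immediate-early list, DNAJB9 at 3.54 and the apoptosis-linked DDIT3 at 2.13 were named after their values were seen. Of 20 p53 targets, 4 rose and 0 fell (5 adjusted over the list alone, median 0.30): PMAIP1 went from 87.8 ± 5.70 to 915 ± 64.5 TMM-scaled CPM (3.37, SE 0.20, adjusted p = 1.34e-14), and PLK2, BTG2, which is also an immediate-early gene, and AEN rose by 4.57, 4.02 and 0.97. Of 10 snoRNA host genes, 7 rose and CCDC104 fell by 0.89 (9 and 1 adjusted over the list alone, median 0.96), with SNHG15 at 1.88 (SE 0.19, adjusted p = 3.85e-09) and TAF1D at 0.77. Of 15 SR splicing factors and CLK kinases, 5 rose and 0 fell (6 adjusted over the list alone, median 0.46): CLK1 at 1.56, SRSF6 at 1.49, SRSF2 at 1.33, SRSF7 at 1.07 and SRSF3 at 0.55. Without culture 1 at 5 min SRSF3 (0.50) and TAF1D (0.69) were not past the test, and SRSF3 was not without any other culture of these times. Members of these lists outside the naming rule were named after their values were seen. None of these lists held with an estimated correlation (adjusted p = 0.143 for stress responses, p53 targets and SR factors, and 0.176 for snoRNA hosts).

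Of 23 histone genes, 13 rose and 0 fell (13 adjusted over the list alone, median 1.71; adjusted p = 0.143 with an estimated correlation). HIST1H4C went from 537 ± 26.8 to 3827 ± 120 TMM-scaled CPM (2.83, SE 0.21, adjusted p = 3.35e-12), below its 7784 ± 1211 at 0 min, and HIST1H2BK rose by 0.60 (SE 0.20, adjusted p = 0.0417), a call lost without culture 2 at 5 min (0.32) or culture 1 or 2 at 30 min (0.52 and 0.67). Of 11 mitochondrial transcripts, 5 rose and 0 fell (7 adjusted over the list alone, median 0.51, adjusted p = 0.218 with an estimated correlation): MT-CO1 at 1.23, MT-ND1 at 1.18, MT-CO3 at 0.78, MT-CO2 at 0.72 and MT-ND2 at 0.67. Zinc finger genes moved little, with ZNF14 at 2.63, ZNF134 at 1.90 and ZNF24 at 0.93 risen of 51 (2 adjusted over the list alone, median 0.27). This list's call was lost with an estimated correlation (adjusted p = 0.388), without culture 1 at 5 min (0.26) and without culture 2 at 30 min (0.16).

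Of 47 respiratory chain genes, 36 fell from 5 to 30 min and 0 rose (42 adjusted over the list alone, median -0.84; adjusted p = 0.203 with an estimated correlation), with COX7A2 at -0.98 (SE 0.20, adjusted p = 0.000928) and ATP5E at -0.80. Of 79 ribosomal protein genes, 35 fell, 0 rose and 44 did not pass the test (51 fell and 1 rose adjusted over the list alone, median -0.55; adjusted p = 0.388 with an estimated correlation), with RPL35 at -0.86 and RPL8 at -0.66. Of 16 glycolysis enzymes, PFKM at -0.90 and ALDOA at -0.59 fell (4 adjusted over the list alone, median -0.40). This list's call was lost with an estimated correlation (adjusted p = 0.309) and without culture 2 at 5 min (-0.28). The largest decreases of single genes were ATP5D, an ATP synthase subunit, at -2.38 (SE 0.74, adjusted p = 0.0306), MEGF11 at -2.28, GTSF1 at -1.70, PSPC1, a paraspeckle protein, at -1.70, KRTCAP2 at -1.59 and ME1, malic enzyme, at -1.49. Without either 30 min culture or culture 1 at 5 min ATP5D (-3.19, -1.86 and -1.91) and MEGF11 (-1.80, -2.98 and -2.02) were no longer past the threshold. The same held for KRTCAP2 without culture 2 at 30 min (-1.17), for GTSF1 without it (-1.31) or culture 2 at 5 min (-1.62), for ME1 without any culture of either time (-1.26 and -1.72 without 5 min culture 1 and 2, -2.01 and -1.11 without 30 min culture 1 and 2), and for ATP5D (-2.32) and ME1 (-1.43) without culture 2 at 15 min. In DESeq2 ME1 did not pass the test, and ATP5D and MEGF11 had no adjusted p. RPL8 lost its call without any culture of either time (-0.58 without culture 2 at 30 min), ATP5E (-0.64 and -0.68) and RPL35 (-0.75 and -0.72) without culture 1 at 5 min or culture 2 at 30 min, and COX7A2 without the latter (-0.88).

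Not called as lists from 5 to 30 min were translation factors (1 rose, 3 fell of 17, but called without culture 2 at 5 min, culture 1 at 15 min or culture 1 at 30 min, -0.32, -0.30 and -0.35), G2 and M phase genes (2 rose, 3 fell of 32, with CKS2 at 1.32), ribosome biogenesis genes (2 and 2 of 39), nuclear noncoding RNAs (2 and 0 of 7) and interferon-stimulated genes (IFIT5 rose by 1.67, of 8, but was not past the test without culture 1 at 5 min, 1.28, or culture 2 at 30 min, 1.46). Adjusted over the list alone these were 1 and 3, 2 and 4, 2 and 2, 2 and 1, and 1 and 0. Heat shock genes went both ways, with HSPA8 at 1.49, DNAJB1 at 1.45, HSPA1B at 1.41 and HSPA1A at 1.28 risen and HSPE1 at -1.11 and HSPB1 at -0.61 fallen (4 and 2 adjusted over the list alone). HSPA1A and HSPA1B are near-identical copies, so their separate counts are uncertain. Of 21 cholesterol biosynthesis genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone), with IDI1 at 1.68, FDFT1 at -0.84 and FDPS at -0.76. For heat shock (-0.07, Up) and cholesterol genes (-0.12, Up) the median and the test differed in sign.

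In total 1295 of 10439 genes differed between 5 and 30 min (edgeR, Benjamini-Hochberg adjusted), 614 higher and 681 lower, of which 509 and 102 by over 2-fold. The called lists had camera adjusted p = 1.34e-90 (immediate-early), 1.37e-25 (respiratory chain), 1.98e-14 (ribosomal proteins), 5.27e-15 (histones), 2.64e-09 (stress responses), 6.21e-07 (snoRNA hosts), 1.33e-05 (mitochondrial transcripts), 0.000171 (SR factors and CLK kinases), 0.00022 (p53 targets), 0.012 (glycolysis) and 0.0167 (zinc fingers). With an estimated correlation none held, at adjusted p = 0.143, 0.203, 0.388, 0.143, 0.143, 0.176, 0.218, 0.143, 0.143, 0.309 and 0.388 in that order. Scaling moved the balance of this comparison, with 767 higher and 311 lower with total counts and 551 and 1122 with RLE. It also turned to more higher than lower genes without any 1 of the 4 cultures compared. Of 498 and 514 genes without culture 1 or 2 at 30 min, 305 and 349 were higher and 193 and 165 lower. Of 750 and 707 without culture 1 or 2 at 5 min, 400 and 403 were higher and 350 and 304 lower. It turned as well without culture 2 at 15 min (612 and 479), with only the 2 times compared (822 and 732), with no low-count filter (691 and 414), at a mean CPM of at least 10 (596 and 587) and on thinned counts (583 and 555).

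The steps between neighbouring times asked when these changes took place. From 5 to 15 min, many immediate-early and histone genes rose while ribosomal and respiratory mRNAs had 0 members past the test. Of 31 immediate-early genes, 15 rose and 0 fell (18 adjusted over the list alone, median 1.54, or 1.45 with genes at 0 counts placed at their bound), with FOS at 6.17 (adjusted p = 2.37e-12, from few counts at 5 min), ID2 at 1.26 and HES1 at 1.45. Of 23 histone genes, 14 rose and 0 fell (18 adjusted over the list alone, median 2.09), with HIST1H4C at 2.22 (SE 0.21, adjusted p = 3.85e-09) and HIST1H2BK at 0.96. The stress genes ATF3, DDIT3, ATF4 and HSPA5 rose by 2.39, 1.26, 0.96 and 0.91 (9 adjusted over the list alone), and the p53 targets BTG2 and PMAIP1 by 2.36 and 2.23 (2 adjusted over the list alone). Of 21 cholesterol genes, MSMO1 and SQLE, both of the late pathway, fell by 1.03 and 0.63 (3 adjusted over the list alone). Neither call was left without culture 2 at 15 min, where 0 genes were lower. ATF3, DDIT3, BTG2 and MSMO1 were named after their values were seen, as were the histone genes that fell from 15 to 30 min.

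From 15 to 30 min, 21 of 31 immediate-early genes rose and 0 fell (29 adjusted over the list alone, median 1.65), with FOS at 1.88 (SE 0.20, adjusted p = 2.12e-07) and NR4A3 at 4.60. Of 47 respiratory chain genes, 33 fell and 0 rose (39 adjusted over the list alone, median -0.89), with COX7A2 at -0.90 and ATP5E at -0.79, and of 79 ribosomal protein genes 19 fell (41 adjusted over the list alone, median -0.46), with RPL35 at -0.82. Of 10 snoRNA hosts, 6 rose (8 adjusted over the list alone), with SNHG15 at 1.24 and TAF1D at 0.63, and of 11 mitochondrial transcripts 5 rose (6 adjusted over the list alone), with MT-ND1 at 0.64. IDI1, an isomerase of the cholesterol pathway, rose by 1.59 (SE 0.18, adjusted p = 7.35e-07). Of 23 histone genes, HIST1H2AC, HIST1H2BN, HIST1H3D and HIST1H1C fell, by 1.54, 1.03, 0.89 and 0.73 (4 fell and 1 rose adjusted over the list alone, median -0.56), whereas HIST1H4C was at 0.61 (SE 0.19, adjusted p = 0.0627).

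From 5 to 15 min 162 genes differed, 108 higher and 54 lower, and from 15 to 30 min 526, 236 higher and 290 lower. The balance moved with scaling, to 138 higher and 36 lower in the earlier step with total counts. In the later step it turned with total counts (315 higher, 202 lower), with only the 2 times compared (513 and 390), without culture 2 at 15 min (118 and 65) and without culture 2 at 30 min (108 and 52). It leaned further down with RLE (198 and 391), in DESeq2 (111 and 359) and without culture 1 at 15 min (125 and 354). Which direction prevailed is thus not settled. The camera lists called in the earlier step were immediate-early genes (adjusted p = 5.14e-53, and 0.0577 as the adjusted p with an estimated correlation), histones (1.75e-47 and 0.0523), stress responses (6.4e-07 and 0.123), p53 targets (0.00353 and 0.123), zinc fingers (0.00392 and 0.349) and cholesterol genes (0.0228 and 0.189). In the later step they were immediate-early genes (1.78e-47 and 0.0577), the respiratory chain (9.74e-44 and 0.123), ribosomal proteins (5.48e-19 and 0.354), snoRNA hosts (2.51e-09 and 0.104), SR factors and CLK kinases (2.37e-06 and 0.0577), mitochondrial transcripts (1.38e-05 and 0.243), stress responses (0.00139 and 0.237), histones and cholesterol genes (0.00222 each, and 0.287 and 0.123), glycolysis (0.0134 and 0.333), translation factors (0.0228 and 0.545) and p53 targets (0.0279 and 0.198). Without culture 1 at 5 min 69 genes differed in the earlier step (61 higher, 8 lower). Without culture 2 at 15 min also 69 did, of which 0 were lower, and without culture 1 at 15 min 106. Without culture 1 or 2 at 0 min 273 and 272 did. In the later step 183, 143 and 160 differed without culture 2 at 15 min and culture 1 or 2 at 30 min.

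Over the 4 times together 6154 of 10439 genes (59.0%) differed by edgeR's F test. Of the markers of other cell types, 2 erythroid and 5 fibroblast genes had enough counts to be tested. TFRC, the transferrin receptor, which dividing cells of many kinds express, fell by 1.03 from 0 to 5 min. SPARC, a matrix protein of the fibroblast list, went from 178 ± 59.4 TMM-scaled CPM at 0 min to 62.0 ± 19.2 at 5 min (adjusted p = 6.8e-06), 64.5 ± 2.56 at 15 min (-1.47, adjusted p = 5.91e-06) and 44.3 ± 1.85 at 30 min (-2.01, adjusted p = 3.37e-08). The galectin LGALS1 of the same list fell by 1.76 from 0 to 5 min. Neither list was called in any comparison.

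The spread between libraries was compared at each level of preparation. Over 8722 genes with a mean of at least 10 CPM, the median SD of log2(CPM + 1) at 30 min was 0.189 between libraries of the same cDNA, 0.308 between cDNA preparations of a culture and 0.333 between cultures. At 5 min these were 0.233, 0.399 and 0.434, at 15 min 0.211, 0.329 and 0.364, and at 0 min 0.274, 0.584 and 0.622. Counting error alone would give 0.289, 0.298 and 0.303 at the 3 levels at 30 min and 0.496, 0.513 and 0.520 at 0 min. Spread between libraries of the same cDNA thus lay below counting error.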

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

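Of the tests in this part, several were chosen only after the results were seen. These were the tests of shared histone reads, the zinc finger list, the shortest genes, the shallow 5 min culture and thinned counts. The test of the difference between the earlier and the later step lay outside the contrasts listed with the edgeR fit. It and the list tests on it are therefore not to be read as set before the data were examined.

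The change from 5 to 15 min differed from the change from 15 to 30 min in 22 of 10439 genes by a test of the difference itself (edgeR, Benjamini-Hochberg adjusted, 1097 at an unadjusted p under 0.05). The difference, earlier step minus later step, was positive in 19 and negative in 3. A positive value can come from a rise in the earlier step or a fall in the later one, and a negative value from the reverse. The steps are also of unequal length. Of the 22, 9 were replication-dependent histone genes, among them HIST1H1C (difference 3.46), HIST1H2AC (3.49), HIST1H1D (4.42) and HIST1H4C (1.61). The immediate-early genes FOS and CYR61 (4.29 and 2.32) rose by more log2 units in the earlier step, for FOS from 5 counts at 5 min, although in TMM-scaled CPM its later gain was the larger (1.77, 165 and 605 at 5, 15 and 30 min). EGR1 was also among the 22, from 3 counts at 5 min. The differences of the cholesterol pathway genes IDI1 (-1.50) and MSMO1 (-1.86) were negative. IDI1 rose in the later step, whereas MSMO1 fell in the earlier one. These examples were chosen after their values were seen. The histone list was called in this contrast with the preset correlation (adjusted p = 3.11e-39) and with an estimated one (adjusted p = 0.0337), the only list of the 20 for which both held. The count was 14, 13, 11 and 16 without culture 1 at 5 min, culture 2 at 15 min, culture 1 at 30 min and culture 2 at 30 min, and 44, 42, 41 and 117 without culture 1 or 2 at 0 min, culture 2 at 5 min and culture 1 at 15 min.

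Histone genes rising mainly in the earlier step might come from reads moving between near-identical copies, or from a single unusual culture. Shared reads would leave the summed share of the list level, but the lowest 15 min culture held 3.73 times the sum of the highest 5 min culture (4132 and 1107 CPM of the total), which argues against it for the rise. A median step difference of 2.04 with either 15 min culture left out (the lower value) argues against a single culture. Why single members fell after 15 min stays open, since the sum did not, 5797 and 6030 CPM at 30 min, owing to HIST1H4C: without it the sums were 2050 and 1658 at 15 min and 1334 and 1294 at 30 min. The incubation time itself, as the design names it, was not tested apart from culture handling and stays open.

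Immediate-early genes rising from 5 to 30 min might reflect the shallow culture 1 at 5 min, a class effect of short genes, or the build-up of short-lived mRNAs in general. Without that culture the list median was 3.34, against the depth of that culture, and the upper quartile of the 1866 protein-coding genes with the shortest span was 1.06, below the lower quartile of the immediate-early list at 2.13: short genes did rise (median 0.27, 322 risen and 156 fallen), but by less, which argues against gene length as the whole cause. A build-up of short-lived mRNAs stays open. The lists of zinc fingers, snoRNA hosts, and SR factors and CLK kinases, also taken as short-lived, had medians of 0.27 (upper quartile 0.73), 0.96 and 0.46. All were called up by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.388, 0.176 and 0.143). The zinc finger call was also lost without culture 1 at 5 min (0.26) or culture 2 at 30 min (0.16). A response of the cells to the label or to handling, which the design ties to the incubation time, was not tested and stays open.

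The fall of short abundant mRNAs and the rise of other genes from 0 to 5 min may come from unspliced RNA among newly made transcripts, from exonic length, or from unequal depth. Given exonic length and mean level, the change correlated with gene span at a partial rank correlation of 0.394 over 9330 genes (0.351 to 0.390 in the 4 pairs of cultures). Unspliced RNA could give this if reads in introns were counted, which was not tested. Other traits that go with span were not separated from it. Given span and level, the change correlated with exonic length at 0.182 (0.164 to 0.180), so a bias with exonic length also stays open as a part of the pattern. Of the calls, 90.8% were also made on counts thinned to the shallowest culture, against unequal depth. The incubation itself, which separates 0 min from the rest, stays open, as does a difference in how the 0 min RNA was prepared, and neither was tested.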

How the results depend on the processing

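Of the tests in this part, those with 1 library per cDNA and those on thinned counts were chosen only after the results were seen. The rest were set before.

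Counts of genes from 0 to 5, 0 to 15 and 0 to 30 min and over the 4 times kept their size: with a replicate block 5592, 5579, 5742 and 5975, in DESeq2 5163, 5035, 5021 and 5437, with 1 library per cDNA 5142, 5170, 5357 and 5715, and thinned to the shallowest culture 5318, 5163, 5350 and 5693. With total counts only they were 5909, 6208, 6953 and 6883. Of these, only 4446, 4417, 4696 and 5150 were also called in the main fit, so which genes were called depended on scaling. Leaving out 1 culture gave 4962 (without 5 min replicate 2) to 5578 (without 30 min replicate 2), 4633 (without 15 min replicate 1) to 5856 (without 5 min replicate 2), 4994 (without 30 min replicate 2) to 6042 (without 5 min replicate 1) and 5630 (without 30 min replicate 1) to 6235 (without 5 min replicate 2). Counts for 5 to 30, 5 to 15 and 15 to 30 min depended on single cultures: 498 (without 30 min replicate 1) to 1627 (without 0 min replicate 1), 69 (without 5 min replicate 1) to 273 (without 0 min replicate 1), and 143 (without 30 min replicate 1) to 659 (without 0 min replicate 2). With a replicate block they were 1203, 151 and 490, with 1 library per cDNA 1261, 200 and 636, thinned 1138, 152 and 463, and in DESeq2 1146, 104 and 470, where the second is lower. With each of the 32 libraries as a sample, which counts technical repeats as samples, they were 2813, 1541 and 2037. The steps gave 483 and 936 in limma-voom with duplicateCorrelation, and 258 and 903 with only the 2 times compared. The cause was not tested.

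Of the 80 list tests 41 were called, 41 with a replicate block, 40 (without 0 min replicate 2) to 42 (without 0 min replicate 1) with a culture left out, and 0 with an estimated inter-gene correlation. With total counts only 43 were called, 16 up and 27 down against 12 and 29, of which 39 were shared: nuclear noncoding RNAs from 0 to 15 and 0 to 30 min (medians 2.08 and 2.27), SR factors and CLK kinases (1.45) and snoRNA hosts (1.85) from 0 to 30 min were gained, and mitochondrial transcripts from 0 to 5 and 0 to 15 min lost. With RLE 42 were, with the translation factors from 5 to 30 min gained (-0.41). With total counts only, the direction turned for ID2 (0.66), HES1 (0.58) and SNHG15 (0.0883) from 0 to 5 min, ZNF24 (0.31) and SNHG15 (0.77) from 0 to 15 min, and SRSF7 (0.46), MT-ND1 (0.65), CKS2 (0.60), TOP2A (0.0582), HSPA5 (0.40), ATF4 (0.72), IDI1 (0.85) and TFRC (0.0266) from 0 to 30 min. The spread (other culture, other cDNA, same cDNA; mean over 5, 15 and 30 min) was 0.219, 0.185 and 0.114 at a mean CPM of at least 100, and 0.309, 0.281 and 0.173 with a pseudocount of 10, against 0.377, 0.345 and 0.211. Spike-in, repeat and spliced or unspliced alternatives were not analysed here, since the table used holds no such entries.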

Other observations

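The tests in this part were chosen only after the results were seen, except the rank correlation of gene span with the 0 to 5 min change, which was set before.

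Among noncoding genes more rose than fell relative to the bulk of genes with TMM scaling. The counts include members of the fixed lists and leave out 912 genes whose symbol had no single match in the annotation. Of those left out, 311 rose and 144 fell from 0 to 30 min, and 55 rose and 50 fell from 5 to 30 min. Of 113 genes annotated as antisense, 48 rose and 7 fell from 0 to 30 min (edgeR, Benjamini-Hochberg adjusted), and 8 rose and 0 fell from 5 to 30 min. Of 50 long intergenic noncoding genes, 26 rose and 3 fell from 0 to 30 min, and 9 rose and 2 fell from 5 to 30 min. Of 9330 protein-coding genes, 2955 rose and 2328 fell from 0 to 30 min, and 538 rose and 629 fell from 5 to 30 min. The difference between the types was not tested, and the balance depends on scaling: over all genes 5622 were higher and 1331 lower with total counts. Without a stated strand, counts of an antisense gene and its partner cannot be separated.

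The relation between gene span and the change had opposite signs from 0 to 5 and from 5 to 30 min. Against 0 min it weakened but stayed positive, with partial rank correlations of 0.394, 0.340 and 0.255 at 5, 15 and 30 min. The 5 min cultures enter 0 to 5 and 5 to 30 min with opposite sign, so a trait of those cultures alone could give both signs. From 15 to 30 min, a contrast without 5 min cultures, it was -0.162 (-0.205 to -0.0743 in the 4 pairs of cultures). From 0 to 5 min the median change was -1.15 in the 1866 protein-coding genes with the shortest span (median 6.69 kb) and 1.62 in the 1866 with the longest (185 kb), where 3.97% and 63.7% rose and 52.1% and 5.25% fell. From 5 to 30 min the same sets of genes had medians of 0.27 and -0.26, and the partial rank correlation with span was -0.280 (-0.316 to -0.168 in the 4 pairs of cultures). A share of unspliced RNA high at 5 min and smaller at 30 min could give this and the 0.394 from 0 to 5 min. It would require that reads in introns were counted, which was not tested. Counts of introns and exons, not analysed here, would test this hypothesis directly. Other traits that go with span were not separated from it. Across genes the values are not independent replicates.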
